A study of Homo sapiens with 4 samples.

How the data were processed

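SMC1 ChIA-PET libraries of Kelly cells were analysed, 2 libraries infected with the shBORIS construct and 2 with the control construct shLUC. ChIA-PET joins DNA fragments held together by an immunoprecipitated protein, here the cohesin subunit SMC1, and reads both ends of each joined fragment as a paired-end tag (PET). Per the labels' protocols, fragments from the immunoprecipitation were ligated by proximity, cut and tagged by transposition, amplified by PCR and size-selected. Reads were trimmed or mapped with tools that include cutadapt 1.8 and Bowtie, on the genome build hg19, per the submitters' processing notes, which give no role or order for them and no Bowtie version. The program that defined anchors and scored interactions, and its settings, are not given in the sources used here.

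The authors deposited 1 table per group, and both libraries of a group name the same table in their labels, so each table was read as the pool of its 2 libraries. The PET count of each anchor pair is named so per the file headers and was taken as an unnormalized count, since the deposited values are whole numbers from 1. The hypergeometric p-value of each pair is the authors' own, per the file headers, which do not say whether it is adjusted, and it was not used for calls. The Bayes probability is named per the file headers, and its deposited values are a fraction between 0 and 1 in steps of 0.001. Only the shLUC table has a header line. The deposited shBORIS table has none and was read in the column order of the shLUC table, since it has the same 9 columns with values of the same kind. Both tables list only pairs with at least 1 PET and use 1 common set of anchors. Of 39507 anchors with a median width of 1172 bp, 39467 occur in both tables, and no 2 anchors overlap. Coordinates are printed with the first base of a chromosome as 1, in hg19.

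An interaction was called when an intrachromosomal pair had at least 3 PETs and a Bayes probability of at least 0.9. Interactions called in both tables were termed shared, those of shLUC alone lost, and those of shBORIS alone gained. Both ends had to overlap by at least 1 bp. Pairs with at least 10 PETs summed over the tables were compared with a two-sided Fisher's exact test of the pair's PETs against the other intrachromosomal PETs, with Benjamini-Hochberg adjustment and a threshold of 0.05. The same test was applied to the summed PETs of each anchor. Scaled ratios divide shBORIS by shLUC PETs after division by each table's total of the same kind, intrachromosomal or interchromosomal. With called interactions alone, the total is that of the pairs called in either group. Intervals are exact 95% Clopper-Pearson intervals, except those of ratios of ratios and of ratios net of random ligation, of the Mantel-Haenszel odds ratio and of the excess at neighbouring anchors, which are normal approximations, on the log scale except for the last. They and the floor of 3 counts cover counting error only, since PETs amplified by PCR without molecular identifiers are not independent molecules. Because the tables pool the libraries, each test compares 2 pools and not the conditions, and no value carries a replicate error.

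Groups, tests, the call minimum, span classes and most alternatives were fixed before the data were examined. The regions named were set by rule: without an annotation of the files' build, the 10 shared interactions with the most PETs, up to 10 with the largest gain and up to 10 with the largest loss past the threshold, and the chromosomes. Regions named outside that rule are said to be so. The test per anchor takes the place of the planned test per gene promoter, which needed hg19 gene positions. The gene table at hand is of GRCh38.p14, and positions were not converted between builds. Promoter contacts, the 18 fixed gene lists and CTCF motifs at anchors were therefore not analysed here, and no gene is named for a region.

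To show what counting alone gives, the pooled PETs of every intrachromosomal pair were assigned at random to the tables in proportion to their totals, 100 times with a fixed seed. That comparison was chosen after seeing the data. The scripts were tested on simulated counts for the comparison of shBORIS with shLUC. Of 200 changed pairs, 50 per fold size, 193 reached the filter and were among the 4505 pairs tested. Of the 50, the pair test called 4% at 2-fold, 36% at 4-fold, 84% at 8-fold and 100% at 16-fold, and it called 6 of 4312 unchanged pairs. Counts were drawn with counting error only. The 200 changed pairs loosen the adjustment, so these shares overstate detection where few pairs change. Over 19623 simulated anchors, the anchor test called 0 without a difference, 0% of 100 anchors changed 2-fold and 11% of those changed 4-fold. Alternatives varied the PET and probability minimum, the overlap rule, the scaling, the filter, the assumed dispersion, the span measure and the intrachromosomal total, to which shBORIS was thinned to match shLUC over 20 draws. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, networkx 3.6.1 and matplotlib 3.10.9 were used.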

Results

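SMC1-bound chromatin interactions were mapped in Kelly, a neuroblastoma cell line, in a derivative resistant to the ALK inhibitor TAE684 and grown in 1 µM of it. BORIS, also called CTCFL, is a paralog of the insulator protein CTCF. The question was how interactions differ after a short hairpin against BORIS relative to a control hairpin. Cells were infected for 24 h and selected for 48 h, with 2 libraries per group. The level of BORIS itself was not analysed here. The pooled shLUC table held 434975 PETs on 374437 anchor pairs and that of shBORIS held 449979 PETs on 378290 pairs. Intrachromosomal PETs numbered 146140 in shLUC, 33.6% of the total (95% interval 33.5 to 33.7), and 163041 in shBORIS, 36.2% (36.1 to 36.4). Most pairs were seen once, 93.5% of those in shLUC and 92.7% of those in shBORIS. With 1 pooled table per group, no difference below could be set against the spread between replicates.

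Of calls with 20 or more PETs, 140 of 140 in shLUC and 186 of 188 in shBORIS were called in both groups. The 10 interactions described next were picked among the shared ones. The pair with the most PETs joined 78963240-78965595 and 78972376-78975497 on chromosome 15, with 73 PETs in shLUC and 114 in shBORIS. Next came a pair on chromosome 12, from 57606467-57610394 to 57630622-57638411, with 57 and 76 PETs. On chromosome 17, 46067619-46075229 contacted 46079167-46083101 with 47 and 79 PETs, and 47937247-47940668 contacted 48071814-48076569 across 135 kb with 42 and 75 PETs. The longest of the 10 strongest spanned 360 kb on chromosome 3, from 187035905-187038784 to 187395885-187398680, with 56 and 49 PETs. None of the 10 strongest shared interactions passed the test. For the chromosome 15 pair the scaled ratio was 1.40 (1.03 to 1.90, Fisher's exact test, adjusted p = 0.747). The remaining 5, on chromosomes 1, 17 and 20, had scaled ratios from 0.808 to 1.31.

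In shLUC 11236 interactions were called and in shBORIS 13111. Of these, 6291 were shared, 4945 were lost and 6820 were gained, so that 56.0% of the shLUC calls (55.1 to 56.9) and 48.0% of the shBORIS calls (47.1 to 48.8) were called in both. After thinning shBORIS to the intrachromosomal total of shLUC, 5373.5 were lost and 5660.5 gained (medians of 20 draws). Sharing followed the PET count. Among shLUC calls with 3 PETs 33.9% were also called in shBORIS, against 97.0% of those with 10 to 19 PETs and 140 of 140 with 20 or more. For shBORIS calls also called in shLUC the values were 25.5%, 94.5% and 186 of 188. Most lost interactions, 70.6%, still had at least 1 PET in shBORIS, and 67.8% of the gained ones had at least 1 in shLUC. Lost and gained interactions had a median of 3 PETs in the table that called them, and shared ones a median of 5 in each table. When pooled PETs were reassigned at random, 6659 ± 38.9 pairs (SD over 100 reassignments) had at least 3 PETs in both tables, where 6399 were observed. At least 3 PETs in shLUC alone were found on 4910 pairs, against 4784 ± 52.1 after reassignment, and in shBORIS alone on 6771, against 6386 ± 63.7. With at least 5 PETs required for a call and 1 PET in the other table counted as shared, 156 were lost and 266 gained.

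Of 3951 pairs tested one by one, 2 were higher in shBORIS and 0 lower. Both joined the anchor at 42383016-42386173 on chromosome 10 to a neighbour. Its contact with 42389829-42395064 had 0 PETs in shLUC and 33 in shBORIS (Fisher's exact test, adjusted p = 5.38e-06). With a floor of 3 counts put in for shLUC the ratio was 9.86, and the exact lower limit was 7.58. The anchor's contact with 42395474-42397430 had 0 and 26 PETs (adjusted p = 0.000124, Fisher's exact test), a ratio of 7.77 at that floor and a lower limit of 5.88. This anchor had no PET of either kind in the shLUC table. Without it, 0 of 3946 pairs passed Fisher's exact test (smallest adjusted p = 0.467) and 220 had an unadjusted p under 0.05. With an assumed negative binomial dispersion of 0.1 neither pair passed (smallest adjusted p = 0.0617 in a test exact for the summed counts), and 60 pairs had an unadjusted p under 0.05. Outside the naming rule, and chosen after their values were seen, a pair on chromosome 12 from 118312167-118313491 to 118313525-118314241 had 18 and 3 PETs (adjusted p = 0.233, Fisher's exact test). A pair on chromosome 1 from 113256755-113262423 to 113351148-113352781 had 2 and 17 (adjusted p = 0.313, Fisher's exact test). Over all tested pairs 225 had an unadjusted p under 0.05, 121 higher and 104 lower in shBORIS, against 143.8 after random reassignment. Changes of 4-fold were often undetectable at this depth. Simulated ones were called in 36% of pairs, but with 200 changed pairs present, which loosens the adjustment. The simulated share is thus an overestimate where few pairs change. In the data a further pair of the chromosome 10 anchor, with 0 and 16 PETs, did not pass (Fisher's exact test, adjusted p = 0.0552). It shows that the adjustment left out even a difference of that size. As 1 pair of an anchor without shLUC PETs, it does not measure how often 4-fold changes were missed.

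**Figure D1:**
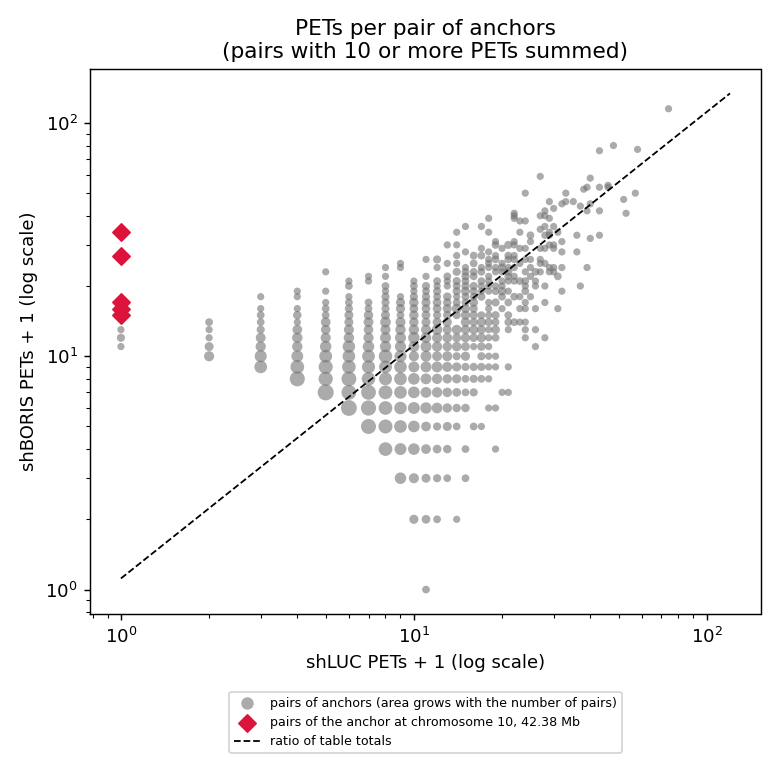
PETs per pair of anchors in shLUC (horizontal) and shBORIS (vertical), each plus 1 on log scales, for the 3951 pairs with at least 10 PETs summed. Grey points grow with the number of pairs, red diamonds are pairs of the chromosome 10 anchor, which lie at 0 PETs in shLUC, and the dashed line is the ratio of the table totals.

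Summed over all its intrachromosomal contacts, the anchor at 46067619-46075229 on chromosome 17 rose from 121 PETs in shLUC to 229 in shBORIS, a scaled ratio of 1.70 (1.36 to 2.13, Fisher's exact test, adjusted p = 0.0146). Its interchromosomal PETs moved with them, from 94 to 189. The anchor at 13958996-13961431 on chromosome 7 fell from 72 to 30 PETs, a ratio of 0.373 (0.235 to 0.579, Fisher's exact test, adjusted p = 0.0146), with 83 and 56 interchromosomal PETs. The anchor at 62477153-62479908 on chromosome 20 rose from 8 to 42, a ratio of 4.71 (2.18 to 11.6, Fisher's exact test, adjusted p = 0.0276), while its interchromosomal PETs numbered 40 and 39. The chromosome 10 anchor had 0 and 126 intrachromosomal PETs. These 4 of 19623 anchors passed, 3 higher and 1 lower in shBORIS, and all were named after their values were seen. With pairs called in either group alone, 9 of 8744 passed, 4 higher and 5 lower. That filter keeps a pair for being high in 1 group, which favours uneven counts. The 9 are therefore no added support. With unadjusted p-values under 0.05 there were 638 anchors higher and 623 lower in shBORIS. The squared deviations between the tables were 1.25 times those of counting error, the only error in the test. The dispersion assumed for the pairs above was not tried for the anchors.

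Contacts under 20 kb took a larger share in shBORIS and those from 100 kb to 2 Mb a smaller share. PETs spanning under 20 kb had a scaled ratio of 1.08 (1.07 to 1.10), and those of 20 to 100 kb 1.03 (1.02 to 1.04). The ratio was 0.981 (0.969 to 0.993) at 100 to 500 kb, 0.954 (0.928 to 0.981) at 500 kb to 2 Mb and 0.886 (0.868 to 0.904) above 2 Mb. Of the PETs above 2 Mb, 91.2% in shLUC and 91.5% in shBORIS were predicted as random ligation from interchromosomal PETs. With predicted random PETs subtracted, the ratio was 1.07 (1.05 to 1.09) under 20 kb, 1.02 (1.00 to 1.03) at 20 to 100 kb and 0.839 (0.664 to 1.06) above 2 Mb, so that the last 2 intervals included 1. The median span was 112.5 kb in shLUC and 102.3 kb in shBORIS, and that of called interactions 64.1 kb and 58.5 kb. The intervals cover counting error only.

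**Figure D2:**
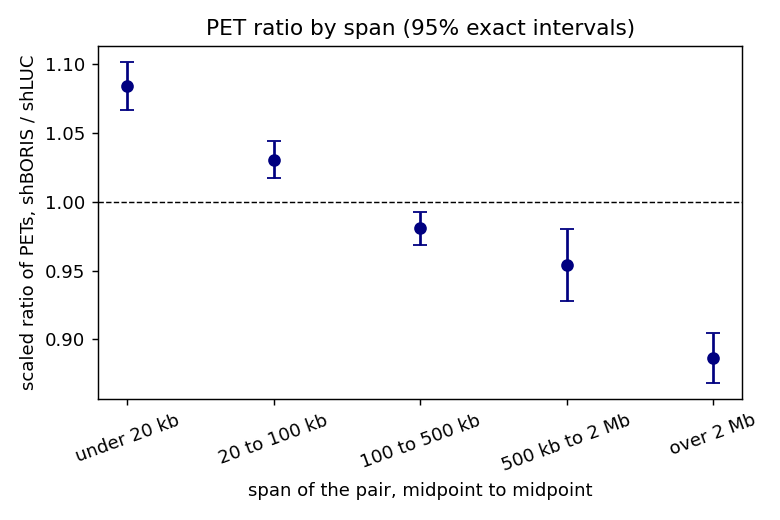
Scaled ratio of intrachromosomal PETs, shBORIS over shLUC, in 5 classes of span between anchor midpoints. Points are ratios, bars exact 95% intervals for counting error, and the dashed line marks 1; the ratio declines from 1.08 under 20 kb to 0.886 above 2 Mb.

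By chromosome, intrachromosomal PETs were lowest in shBORIS relative to shLUC on chromosome 4, with a scaled ratio of 0.849 (0.809 to 0.890), and on chromosome 13, with 0.882 (0.826 to 0.943). They were highest on chromosome 19, at 1.12 (1.07 to 1.16), chromosome 16, at 1.10 (1.04 to 1.18), and chromosome 17, at 1.06 (1.04 to 1.09). For interchromosomal PET ends the ratio was 0.967 on chromosome 4, 0.939 on chromosome 13, 1.07 on chromosome 19, 1.06 on chromosome 16 and 1.04 on chromosome 17. Across 23 chromosomes, which are not replicates, the log2 ratios of the 2 kinds correlated with Pearson's r = 0.80 and Spearman's rho = 0.80 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). Without the 2 chromosomes farthest from the median r was 0.72. Chromosome 17 had the densest calls, 46.8 per 100 anchors in shLUC and 54.9 in shBORIS, and chromosome X the sparsest, 10.7 and 11.2.

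**Figure D3:**
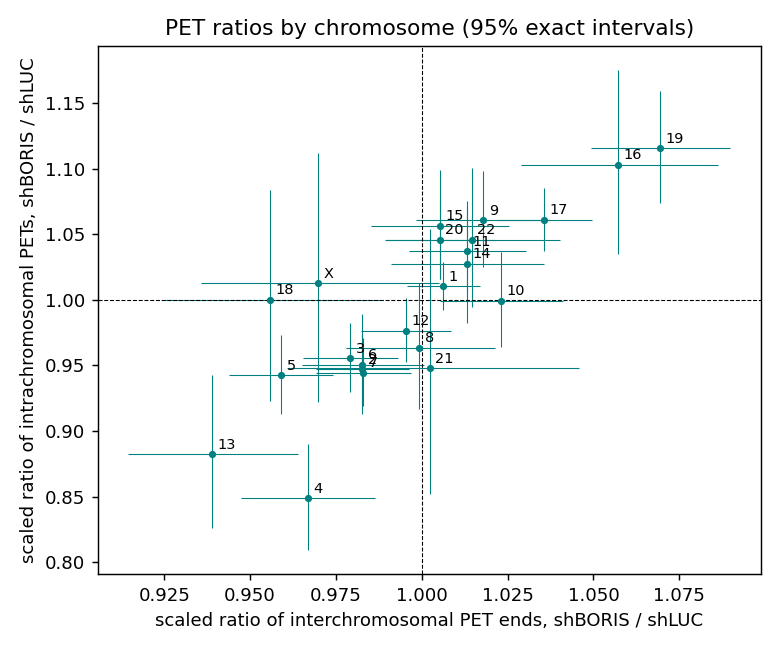
Scaled ratio of intrachromosomal PETs (vertical) against that of interchromosomal PET ends (horizontal), shBORIS over shLUC, 1 point per chromosome with exact 95% intervals for counting error. Chromosomes 4 and 13 lie lowest and chromosome 19 highest on the vertical axis.

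The most connected anchor, at 71634009-71644664 on chromosome 17, had 16 called interactions in shLUC and 22 in shBORIS. At 71704418-71710475 on the same chromosome there were 11 and 16, whereas 43450434-43459284 on chromosome 2 had 15 and 14, and 184278135-184282573 on chromosome 3 had 15 and 11. These anchors were named after their values were seen. The largest linked cluster of each table lay on chromosome 17, with 69 anchors between 68762512 and 71367169 in shLUC and 134 anchors between 70552267 and 72955005 in shBORIS. These ranges overlap only in part, and cluster size was not compared at equal depth. Of anchors with a call, 475 of 13543 had 5 or more in shLUC, or 3.51% (3.20 to 3.83), and 744 of 14460 in shBORIS, or 5.15% (4.79 to 5.52). After thinning shBORIS to the intrachromosomal total of shLUC its share was 4.48%. With pairs of at least 3 PETs in place of calls, the difference was 1.62 percentage points, and random reassignment of pooled PETs gave 0.677 ± 0.182 (SD, 100 reassignments) with a maximum of 1.09.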

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

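Interchromosomal PETs, which the comparisons above use only as a reference, were tested per anchor after the data had been seen, and all 3 tests of the chromosome 10 anchor were likewise chosen after its result was seen, the one on read placement once that on omission had come out; the criteria for omission and for lost contacts were later narrowed, since neither a shift of the neighbours nor an unlisted anchor decides them. Of 35637 anchors tested with Fisher's exact test, 5 were higher in shBORIS than in the control and 0 lower, and 1981 had an unadjusted p under 0.05. The anchor at 42383016-42386173 on chromosome 10 had 475 such PETs in shBORIS and 0 in shLUC, a ratio of 159 at the floor of 3 counts and a lower limit of 129. On chromosome 17, 46067619-46075229 had 189 against 94, a scaled ratio of 2.02 (1.57 to 2.62). On chromosome 1, 204326759-204329945 had 78 against 25, a ratio of 3.14 (1.98 to 5.14). On chromosome 12, 58025823-58027671 had 46 against 11, a ratio of 4.21 (2.15 to 9.01). On chromosome 19, 11319089-11322802 had 73 against 28, a ratio of 2.62 (1.68 to 4.22).

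The chromosome 10 anchor carried 601 PETs in shBORIS, the most of any anchor there, and 0 in shLUC, while no other anchor listed in 1 table alone had more than 13. A loss of its contacts in shLUC without a loss of coverage would leave about 478 interchromosomal PETs by scaling, and 0 are listed, but an anchor missing from the table would show the same, so this stays open. Placement of its reads at the other 11 anchors between 42 and 43 Mb would account for 27.1% (10.2 to 43.9, normal approximation to counting error) of its scaled PETs, and for the whole those anchors would need a ratio of 1.55 of their own, above the highest (1.32) and the central 95% range (0.853 to 1.21) of 530 other regions of 1 Mb with at least 1000 PETs. Omission of the anchor from the shLUC table may account for the 0 and stays open. At those 11 anchors the scaled ratio was 0.883 (0.817 to 0.955), inside the central 95% range of the other regions. Its interval leaves out 1, which the criterion for omission had asked for. The ratio does not decide omission, since omission leaves the neighbours free. Reads placed elsewhere in the genome and a difference between the groups stay open too.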

How the results depend on the processing

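Alternatives without the chromosome 10 anchor were chosen after the data were seen; the others were planned. Of 56 alternatives over 16 results, 41 stayed within 1.5 times the main count or inside its counting interval and 15 moved beyond it. Reversal was scored for the span ratios only, where 0 reversed. Some of the 41 could not have changed. The groups have identical anchors, so a stricter overlap gave the same sets, and the chromosome 10 anchor had 0 PETs in shLUC to remove. With at least 5 PETs, called interactions numbered 4439 in shLUC and 5315 in shBORIS, and anchors with 5 or more calls made up 1.15% and 2.14%; with 5 PETs in 1 table and 1 in the other, 156 were lost and 266 gained. The first 4 values follow from the higher minimum, the last 2 from that and the looser rule for sharing together. The 2 pairs past the threshold became 0 without pairs under 20 kb (smallest adjusted p = 0.102), 0 with a negative binomial dispersion of 0.1 (0.0617) and 0 without the chromosome 10 anchor (0.467); unadjusted p-values under 0.05 numbered 136, 60 and 220. Both passing pairs span under 20 kb and hold that anchor. Other scalings and filters gave 2 or 3, with a smallest adjusted p between 1.21e-06 and 0.000201. Anchors past the threshold numbered 9 (4 higher) with pairs called in either group and 3 without the chromosome 10 anchor. Calling uses the same counts and keeps a pair that is high in 1 group, which can raise the 9. How much it did so was not tested. On pairs called in either group the span ratios were 1.04, 1.01, 0.951 and 0.944 up to 2 Mb. Above 2 Mb the ratio was 0.744, where 10 pairs with 42 and 36 PETs remain. These ratios were scaled to the PETs on such pairs and not to all intrachromosomal PETs. Their level is therefore not comparable with that of the main ratios. The intervals at 20 to 100 kb (0.997 to 1.03) and above 500 kb (0.886 to 1.01, 0.463 to 1.19) include 1. How much of the shift comes from the changed total was not tested. Thinning shBORIS to the intrachromosomal total of shLUC gave 11521 calls, 5862.5 shared, 5373.5 lost and 5660.5 gained (medians of 20 draws), and 4.48% of anchors with 5 or more calls. The Bayes probability was not recomputed in thinning. No paired analysis was possible because each table pools the 2 libraries of its group, so no replicate block or left-out replicate was run. Promoter windows, gene list settings and motif settings were not run. Depth limits the pair test to large changes.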

Other observations

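The windows, the clusters of distant PETs and the tests of neighbouring anchors, of the share under 20 kb net of random ligation, of the chromosome 15 and X pair, of the starts of chromosomes 11 and 17 and of the chromosome 2 and 5 junction were chosen after results had been seen. In windows of 500 kb, 11 of 3254 passed Fisher's exact test on PETs under 2 Mb, 6 higher and 5 lower in shBORIS, and 277 had an unadjusted p under 0.05. The smallest p was at 42 to 42.5 Mb of chromosome 10, with 51 and 150 PETs, a window that holds the anchor without PETs in shLUC. Windows of 250 kb gave 6 and windows of 1 Mb gave 9. Chromosome 7 from 13.5 to 14 Mb fell from 105 to 49 PETs, a scaled ratio of 0.411 (0.287 to 0.583), while its interchromosomal ratio was 0.707. That window holds the anchor at 13958996-13961431 named above, with 72 and 30 intrachromosomal PETs, so it is not a separate observation. Chromosome 10 from 54 to 54.5 Mb fell from 63 to 30, a ratio of 0.420 (0.262 to 0.658), with an interchromosomal ratio of 0.917 (0.726 to 1.16). Of these, 28 PETs in shLUC and 3 in shBORIS joined the 3 anchors at 54380961-54382505, 54391148-54392760 and 54399017-54400209. Chromosome 17 from 48 to 48.5 Mb rose from 284 to 431, a ratio of 1.34 (1.15 to 1.56), with an interchromosomal ratio of 0.987 (0.895 to 1.09). The windows at 69 to 69.5 Mb of chromosome X and 74 to 74.5 Mb of chromosome 5 each rose from 1 PET to 18, a ratio of 15.9 (2.51 to 661).

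A small number of distant parts of the genome were joined by more PETs than predicted, most of them with PETs in both groups. Of 176663 pairs of 1 Mb bins at least 10 Mb apart on the same chromosome, 11 passed a Bonferroni threshold. Among these, 8422332-8826878 and 84249515-84250764 on chromosome 2 were joined by 0 PETs in shLUC and 5 in shBORIS. Between chromosomes the prediction used anchor coverage, and within them it was also scaled to the observed PETs of each chromosome and distance class. On chromosome 5, 38265145-38569732 and 76163392-76942102 were joined by 34 PETs in shLUC and 29 in shBORIS, where 0.769 were predicted for both together. On chromosome 9, 101025571-101080277 and 123110707-123240279 were joined by 16 and 7, against 0.267. The top anchor pair held 47.8% of the PETs of this chromosome 9 cluster and 22.2% of those of the chromosome 5 cluster. Of 3580620 pairs of 1 Mb bins on different chromosomes, 12 passed a Bonferroni threshold, 11 of them with PETs in both tables. The part of chromosome 10 from 42383016 to 42600706 was in 2 of these, with 196263949-196951743 on chromosome 3 (13 PETs in shLUC and 16 in shBORIS against 2.90) and with 92269236-92320615 on chromosome 2 (3 and 7 against 0.527). Whether reads were misplaced was not tested for these 2, nor for the clusters within chromosomes.

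Between chromosomes, the largest excess in number of PETs, though not in ratio to the prediction, joined 29178862-29930097 on chromosome 2 to 1167327-1645803 on chromosome 5. It held 33 PETs in shLUC and 24 in shBORIS against 1.47 predicted. Its PETs lay on 40 anchor pairs and at most 7.02% on any 1 of them, which argues against reads misplaced between a pair of similar sequences. A junction of these chromosomes in this cell line may account for it, as a hypothesis not tested on DNA reads. By contrast, 20 PETs between chromosomes 15 and X lay 100% on 1 anchor pair. Between 189251-192971 on chromosome 11 and 13818-656170 on chromosome 17, 55.6% of 18 PETs lay on 1 pair. The top pair also held 56.25% of 16 PETs between 134035991-134037591 on chromosome 10 and 166554775-166731708 on chromosome 2. It held 52.4% of 21 between 149192311-149225439 on chromosome 1 and 91759401-91819651 on chromosome 2. The clusters of chromosomes 10 and 1 were added after their values were seen. Misplaced reads may account for each of these clusters. Of 23 PETs between 114270450-114646363 on chromosome 11 and 39150137-39824218 on chromosome 17, 21.7% lay on the top pair, which leaves misplacement open.

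The larger share of short spans in shBORIS was set against 3 technical explanations. More random ligation in shLUC is argued against as the whole cause: net of predicted random PETs the share ratio under 20 kb fell from 1.08 to 1.07 (1.05 to 1.09), and its quotient with that at 100 to 500 kb, classes with under 0.5% predicted random PETs, was 1.11 (1.08 to 1.13). An excess of neighbouring anchors under 20 kb alone is argued against by the ratio at 20 to 100 kb over that at 100 to 500 kb, 1.05 (1.03 to 1.07). Unequal coverage of chromosomes is argued against by a Mantel-Haenszel odds ratio of 1.10 (1.07 to 1.12) within chromosomes, above 1 on 22 of 23. Fragment size or fixation may differ between the library pools, which was not tested, and the hairpin and the pool cannot be separated with 1 table per group.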
